A study of Mus musculus with 6 samples.

How the data were processed

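Gene expression was measured in mouse T cells with 2-colour Agilent oligonucleotide arrays. The samples were splenic CD4+ CD62L-high CD25-negative naive T cells from Irf4 null (Irf4 -/-) and heterozygous (Irf4 +/-) mice, cultured for 42 h under conditions that polarize cells toward the Th17 fate. Per the labels' protocols, the culture held plate-bound anti-CD3, anti-CD28, IL-6, IL-23, TGF-beta and antibodies that block IL-4 and interferon gamma. Each group had 3 samples, which the design text calls biological replicates. Whether these were separate animals or separate cultures is not given in the sources used here, so the p-values measure the spread between these samples. Groups were taken from the sample titles and the stated genotypes. The free-text description of heterozygous replicate 3 gives a genotype that can be read in more than 1 way, while its title and genotype fields both place it in the heterozygous group.

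Per the labels, every sample was labelled with Cy5 and hybridised against a common reference labelled with Cy3, a commercial RNA pool from several mouse tissues, with no dye swap. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7 and processed with Partek. The deposited value table holds log2 ratios of sample to reference for 22749 probes, which the header of the authors' deposited table of results calls normalized. The base of the logarithm and the direction between genotypes were settled from the values: differences of group means matched the log2 of the authors' deposited fold changes within 1.03e-05 for all 828 listed probes. The direction of sample over reference rests on the dye labels. Intensities, background flags, slide positions and scan dates were not used here, so no filter on dim probes and no test for a slide or scan batch could be made. The number of arrays limits the precision of every value.

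The authors' deposited table lists p-values and fold changes for 828 probes, made per the file headers with a 1-way ANOVA in Partek Genomic Suite 6.6 and restricted to probes with over 2-fold change and an unadjusted p-value under 0.05. Gene symbols were paired with probes only in this table. Of its probes, 816 had a symbol and 12 had none, and 21933 probes are unnamed here. Old symbols were updated through the names and synonyms of a RefSeq gene table of the assembly GRCm38.p6. Of 689 symbols, 543 were current, 113 were updated through a synonym, 2 matched several genes, and 31 were unmatched. Symbols of the last 2 kinds were kept as listed. This gave 688 named genes, and every one of them had already been selected for a difference between these samples.

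Listed probes of 1 gene were averaged, which left 22621 genes and unnamed probes for testing. Any other probe of a named gene stayed as an unnamed row. The value of a gene therefore rests only on probes selected for change, and 1 gene can count in more than 1 row. The listed probes of 111 genes numbered over 1, and those of 1 gene, Serpinb1b, disagreed in direction. Null and heterozygous samples were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates and without further normalization, and p-values were adjusted by the Benjamini-Hochberg method over all 22621 tests. The threshold was an adjusted p under 0.05. Fold changes are of null over heterozygous cells. Named in the text by a rule set before the data were examined were Irf4, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap, up to 4 members of each gene list past the threshold or up to 2 where none passed, and 22 genes of T cell programmes. Of those 22, only 6 had a named probe. Some items are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

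Before the data were examined, 31 gene lists with 699 different genes were fixed for T cell programmes, signalling, metabolism and markers of other cell types. Of these genes, 83 were named here. The planned competitive list test (camera, with a preset and with an estimated correlation) and the rotation test (fry) were not run, because list members could be recognised only among probes selected for change. A count adjusted over the list alone, and a test of overlap with the authors' deposited table, were left out for the same reason. In their place, a two-sided Fisher's exact test compared the share of higher members with that of the other named genes, for the 18 lists with at least 3 named members, and was adjusted over those lists by the Benjamini-Hochberg method. This test asks only about direction among selected genes.

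The limma step was tested on simulated data for 22621 rows, of which 50 were changed at each of 4 sizes. The rows had the heterozygous means, 1 spread per row for both groups, and noise independent between rows. In the real arrays the number of changed rows is not known and whole arrays can deviate, so the figures need not carry over. The limma step recovered 30% of rows changed by 1 on the log2 scale, 58% at 2, 80% at 3 and 96% at 4. This gave 15, 29, 40 and 48 calls in the right direction at the 4 sizes, beside 13 false calls among 22421 unchanged rows. The false calls were a larger share of all calls than the adjusted threshold aims for. With nothing changed there were 0 calls. With 1 null array left out of the same simulation, recovery was 2%, 42%, 64% and 86%. The list and neighbour tests were also tested on simulated data.

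The alternatives tried were array centring, quantile normalization, testing single probes, taking the least variable probe of a gene, leaving out the most variable 25% of probes, robust variance estimation, array weights, the methods' t-test, fold minimums of 1.5 and 2, an adjusted threshold of 0.1, the replicate number as a block, and leaving out each sample in turn. Log2 ratios of exactly 0 treated as missing, and arrays scaled to 1 spread, were added after the data were seen. Ratios of exactly 0 occurred on at least 1 array for 2125 probes and can be failed estimates. Figures and tables were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The gene table was also used for the order of genes along chromosomes, without coordinates, since the sources used here name no genome build.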

Results

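Expression was profiled on 6 arrays, 3 of Irf4 null and 3 of Irf4 heterozygous T cells, after 42 h under Th17-polarizing conditions. Irf4 encodes a transcription factor of activated lymphocytes. The comparison asks which transcripts differ between Th17-polarized cells without and with a functional copy of this gene. Each array held 22749 probes with no missing value, and array medians lay between -0.03 and 0.06 on the log2 scale. The SD of the log2 ratios was 1.61, 1.68 and 1.83 on the null arrays and 1.74, 1.76 and 1.74 on the heterozygous arrays. Across probes, which are not independent replicates, arrays of the heterozygous group correlated at r = 0.952 to 0.964. Among null arrays, replicates 2 and 3 correlated at 0.961, and replicate 1 correlated with them at 0.936 and 0.915. Null replicate 3 correlated with the heterozygous arrays at 0.930 to 0.938, above its correlation with null replicate 1. Null replicate 1 also carried the most ratios of exactly 0, at 5.28% of probes, against 0.673% on heterozygous replicate 2.

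**Figure D1:**
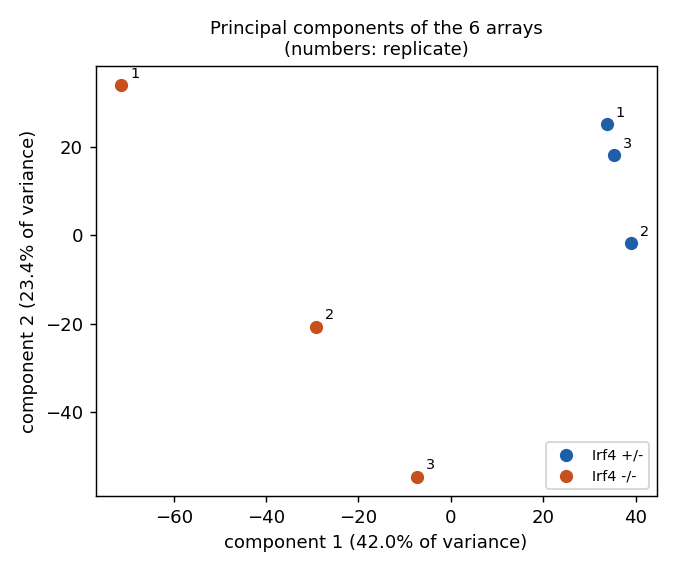
Principal components of the log2 ratios of the 6 arrays, with 1 point per array, coloured by genotype and numbered by replicate; the axes give the score on components 1 and 2. The null arrays have component 1 scores of -71.4, -29.2 and -7.4, and the heterozygous arrays lie between 33.8 and 39.0.

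The targeted gene was lower in each null sample. The log2 ratio of Irf4 to the reference was 0.62, 0.65 and 0.73 in null replicates 1, 2 and 3, and 3.02, 2.85 and 2.93 in the heterozygous replicates. The group means were 0.67 ± 0.06 and 2.93 ± 0.08 (SD, n = 3 each). Irf4 was 4.81-fold lower in null cells, with a log2 fold change of -2.27 (SE 0.12, 95% confidence interval -2.55 to -1.98) and a limma Benjamini-Hochberg adjusted p of 0.00351. It passed the threshold in each of the 6 fits that left out 1 sample. The sources used here do not give the deleted part of the gene or the position of its listed probe.

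The largest falls in null cells included transcripts for a cytokine and for surface receptors. The largest rises included transcripts for a secreted protease, a transcription factor and a matrix protein. These are single genes picked for size and do not give a direction for a class. Among named secreted cytokines and chemokines past the threshold, 7 fell and 3 rose. Il9, which encodes interleukin 9, fell from a log2 ratio of 9.15 ± 0.06 in heterozygous cells to 4.63 ± 0.82 in null cells (SD, n = 3 each), a 23.0-fold decrease with a limma adjusted p of 0.00965. Procr, which encodes the protein C receptor, fell 19.2-fold, and Ltb4r1, which encodes a leukotriene B4 receptor, fell 14.3-fold. In the other direction Mmp13, which encodes a collagenase, rose from -2.71 ± 0.54 to 3.43 ± 0.13, a 70.1-fold increase with an adjusted p of 0.00257. Twist1, a basic helix-loop-helix transcription factor, rose 28.5-fold, from a mean log2 ratio of -5.10 to -0.265. Spp1, which encodes osteopontin, rose 20.9-fold, from -8.87 to -4.49, and so stayed below the reference in both groups. No filter on dim probes could be made, so how far these values lie above background is unknown.

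In all, 551 of 22621 genes and unnamed probes passed the threshold, 286 of them higher and 265 lower in null cells. Of these, 357 were named genes, 189 higher and 168 lower, and 194 were unnamed probes. An unadjusted p under 0.05 was found for 4615, and the groups did not overlap for 6739, where chance gives 10%. The number past the threshold was 184, 30 and 239 without null replicate 1, 2 or 3, and 80, 186 and 46 without heterozygous replicate 1, 2 or 3. Of the 357 named genes, 26 passed in all 6 such fits and 87 in none.

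Among the 12 named genes with the largest falls, Havcr1, a costimulatory receptor of the TIM family, fell 15.6-fold (log2 fold change -3.96, SE 0.29, adjusted p = 0.00701). Cd5l, which encodes a secreted scavenger-receptor protein, fell 13.9-fold. Its neighbour in the genome, Fcrl1, an Fc receptor-like gene, fell 14.0-fold. Stard8 fell by 3.70 on the log2 scale, and Plk5, a member of the polo-like kinase family, fell 12.9-fold. Klre1, an NK cell receptor gene, fell 11.9-fold, with an adjusted p of 0.0388 that became 0.0771 when its null value of exactly 0 was treated as missing. Abp1, a listed symbol that matches more than 1 current gene, fell by 5.64 on the log2 scale. Gja3, a connexin gene, was listed at exactly 0 on all 3 null arrays and at 5.35, 5.56 and 6.01 on the heterozygous arrays. Ildr1 was listed at 0, 1.43 and 0 in null replicates 1, 2 and 3, against 5.15, 5.41 and 4.86 in heterozygous cells. Havcr1, Fcrl1 and Abp1 each had 1 null value of exactly 0 and stayed past the threshold without it, with limma adjusted p-values of 0.0167, 0.00362 and 0.00975. Abp1, Procr, Ltb4r1 and Fcrl1 passed in all 6 fits that left out 1 sample, while Plk5, with an adjusted p of 0.0444 from all samples, and Klre1 passed in 0 of them.

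Among the 12 named genes with the largest rises, Ano1, which encodes a calcium-activated chloride channel, rose 33.1-fold (log2 fold change 5.05, SE 0.38, limma adjusted p = 0.00701). Apol7c, an apolipoprotein L gene, rose 28.5-fold. Ccl1, which encodes a chemokine of activated T cells, rose from a log2 ratio of -0.06 ± 0.82 to 4.12 ± 0.33 (SD, n = 3 each), a log2 fold change of 4.17. Dppa1 rose 19.7-fold. The interferon-inducible genes Ifi206 and Gbp6 rose 14.0-fold and 12.1-fold. Calhm6, Fam110c and Ms4a6d rose 12.7-fold, 12.3-fold and 11.0-fold. Ifi206 had 1 heterozygous value of exactly 0, and its adjusted p of 0.0383 was 0.0367 without it. Mmp13, Ano1, Twist1, Apol7c and Spp1 passed in all 6 fits that left out 1 sample, while Dppa1, Ifi206, Fam110c and Gbp6 passed in 1.

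**Figure D2:**
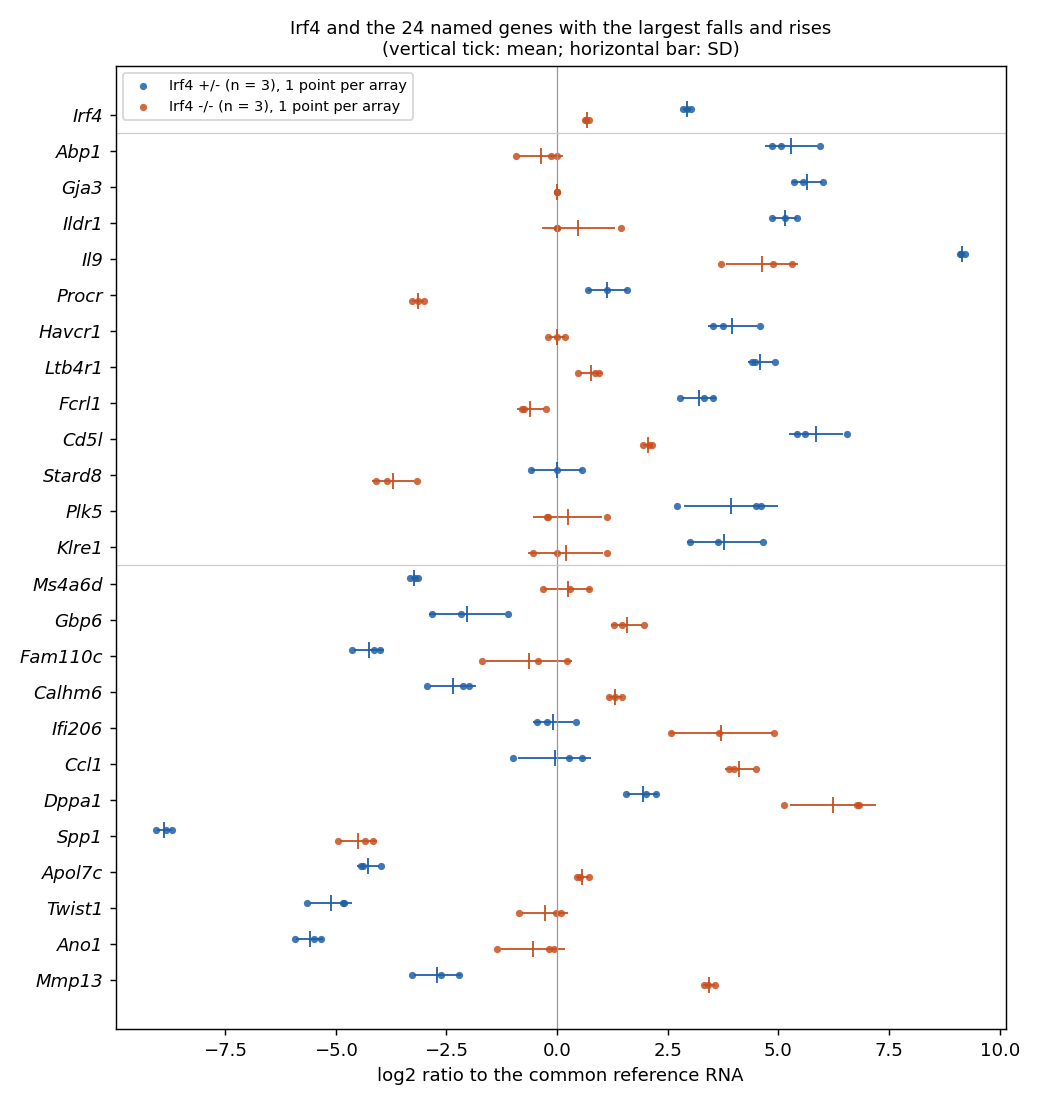
Log2 ratio to the common reference RNA (horizontal axis) for Irf4 and the 12 largest falls and 12 largest rises among named genes, with 1 point per array, a vertical tick at the group mean and a bar of 1 SD (n = 3 per genotype). The 3 null values lie apart from the 3 heterozygous values for each gene, by rule; Gja3 is listed at exactly 0 on all 3 null arrays.

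Of 26 genes fixed as Th17-associated, 11 were named here, all of them selected by the authors for change. Of these 11, 6 fell, 0 rose and 5 did not pass; 10 had a negative and 1 a positive log2 fold change (Fisher's exact test p = 0.0121, adjusted p = 0.218 over 18 lists). Beside Il9, the cytokine genes Il22, Il10 and Il24 fell 9.70-fold, 9.67-fold and 7.12-fold, with limma adjusted p-values of 0.00995, 0.00995 and 0.0262. Il9 and Il22 passed in 4 of the 6 fits that left out 1 sample, Il10 in 3 and Il24 in 1. The other members that fell, named after their values were seen, were Tnfrsf13b and Il12rb1, with limma adjusted p-values of 0.0188 and 0.00855. Il21, a cytokine gene of Th17 and follicular helper cells, had a log2 fold change of -2.99 (SE 0.59, adjusted p = 0.0638). Il23r, which encodes the IL-23 receptor, had -1.59 (SE 0.45, adjusted p = 0.13). Il1r1, chosen after its value was seen, had the positive value of 1.09 (adjusted p = 0.0691). No probe was named here for Il17a, Il17f, Rora, Batf, Maf, Ahr, Stat3, Foxp3, Tbx21, Bcl6, Prdm1, Ifng, Il4, Irf8 or Ikzf3, so their levels are not known. Every probe past the authors' 2 limits is listed, and none carries these symbols, though 12 listed probes have no symbol. A gene without a probe on the array would look the same as one whose change fell short of either limit.

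Of 46 genes fixed as type I interferon-stimulated, 8 were named here, likewise selected for change. Of these 8, 6 rose, 1 fell and 1 did not pass (Fisher's exact test p = 0.0305, adjusted p = 0.274). Samd9l rose 6.23-fold and Rtp4 rose 5.37-fold. Oasl2, an oligoadenylate synthetase-like gene, rose with a log2 fold change of 2.32, and Ifih1, which encodes the RNA sensor MDA5, rose 4.36-fold, with limma adjusted p-values of 0.00924 and 0.00619. Irf9, which encodes the DNA-binding subunit of the interferon-activated ISGF3 complex, fell 2.29-fold (adjusted p = 0.0262). Both named members of the IRF family list, Irf4 and Irf9, fell. Irf4 and Ifih1 passed in all 6 fits that left out 1 sample, Rtp4 and Oasl2 in 4, Samd9l in 2 and Irf9 in 0.

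Named genes of other T helper programmes that passed included both rises and falls. Of 13 named secreted cytokines and chemokines, 3 rose and 7 fell. Il2, which encodes the T cell growth factor interleukin 2, fell 3.89-fold with an adjusted p of 0.0477. Among 5 named Th2 genes, 3 rose and 1 fell: Gata3, the main Th2 transcription factor, rose 2.84-fold (log2 fold change 1.51, SE 0.15, limma adjusted p = 0.0121), Areg, which encodes amphiregulin, rose 4.34-fold, Dusp6 rose 2.95-fold, and Il24 fell. Among 4 named Th1 and cytotoxic genes, Nkg7 rose 4.95-fold and Runx3, a transcription factor of cytotoxic and Th1 cells, fell 4.39-fold. Of 7 named Treg genes 2 rose and 2 fell: Nrp1 rose 3.74-fold and Nt5e, which encodes the ectoenzyme CD73, rose 2.88-fold, whereas Ebi3 fell 4.24-fold and Ikzf2, which encodes Helios, fell 3.42-fold. Tox, a transcription factor gene in the follicular helper and inhibitory receptor lists, rose 5.37-fold (adjusted p = 0.00351). It was the 1 named follicular helper gene of 3 past the threshold, and with Il10 1 of 2 among 5 named inhibitory receptor and terminal effector genes. Of 4 named naive and quiescence genes, Ly6c1 fell 2.39-fold. Its probe is listed under the older symbol Ly6c. In the 6 fits that left out 1 sample, Tox passed in all 6, Runx3 in 4 and Gata3, Ebi3 and Ikzf2 in 3. Dusp6 passed in 2, and Il2, Il24, Areg, Nkg7, Nrp1, Nt5e and Ly6c1 in 1. No named chemokine receptor or homing integrin of 4 passed, and Gpr15 and Ccr6 had log2 fold changes of -3.07 (adjusted p = 0.0558) and -2.45 (adjusted p = 0.116). The direction test of these lists gave adjusted p-values of 1.0.

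Named signalling, metabolic and survival genes that passed also included both rises and falls. Among 5 named TGF-beta response genes, Smad3 fell 2.49-fold, Pmepa1 fell 2.03-fold and Nrp1 rose. Among 5 named immediate early genes of T cell receptor signalling, Dusp6, Spry1 and Rcan1 rose, the latter pair 2.43-fold and 2.15-fold, and Tnfaip3, which encodes the NF-kappaB inhibitor A20, fell 2.12-fold. In the apoptosis list, with 5 named members, Tnfsf10, which encodes TRAIL, rose 6.06-fold, Bbc3, which encodes PUMA, rose 2.62-fold, and Bcl2l1, which encodes the survival protein Bcl-xL, fell 2.13-fold. Scd2, a fatty acid desaturase gene, fell 5.80-fold, 1 of 2 named sterol and fatty acid genes. Nupr1, the 1 named ATF4 gene, rose 4.76-fold, and Ccnd1, the 1 named cell cycle gene, rose 2.11-fold. In the 6 fits that left out 1 sample, Nupr1 passed in all 6, Scd2 in 4, and Dusp6 and Bbc3 in 2. Smad3, Pmepa1, Nrp1, Tnfaip3 and Tnfsf10 passed in 1, and Spry1, Rcan1, Bcl2l1 and Ccnd1 in 0. All 5 named glycolysis and hypoxia genes had negative values and 0 passed (Fisher's exact test p = 0.0631, adjusted p = 0.379); Slc16a3 and Egln1 had log2 fold changes of -1.57 (limma adjusted p = 0.132) and -1.07 (adjusted p = 0.0548). Hyou1, the 1 named stress protein gene, had 1.33 (adjusted p = 0.141). The direction tests gave adjusted p-values of 0.707 for the immediate early and apoptosis lists and 1.0 for the TGF-beta list. No member was named for the lists of cytokine receptor and STAT feedback genes, AP-1 and BATF genes, or ribosome biogenesis and MYC genes.

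Named markers of other cell types that passed included both rises and falls. Cd24a fell 5.24-fold and Sdc1, a plasma cell marker, rose 2.63-fold, out of 3 named B cell and plasma cell markers. Cd86 fell 5.45-fold and H2-DMb1 rose 2.35-fold, out of 3 named dendritic cell and MHC class II genes. Hemgn, the 1 named erythroid gene, fell by 3.26 on the log2 scale with 1 null value of exactly 0 (limma adjusted p = 0.0098, and 0.0165 without that value). Klre1 was the 1 of 3 named CD8 T cell and NK cell markers past the threshold, and Gata3 the 1 of 3 named T cell identity genes. In the 6 fits that left out 1 sample, Cd24a and Hemgn passed in 4, and H2-DMb1 and Gata3 in 3. Cd86 passed in 2, Sdc1 in 1 and Klre1 in 0. No member was named for the gamma-delta T cell, monocyte and granulocyte, platelet, or stromal lists. The direction test gave an adjusted p of 1.0 for each marker list it could test.

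**Figure D3:**
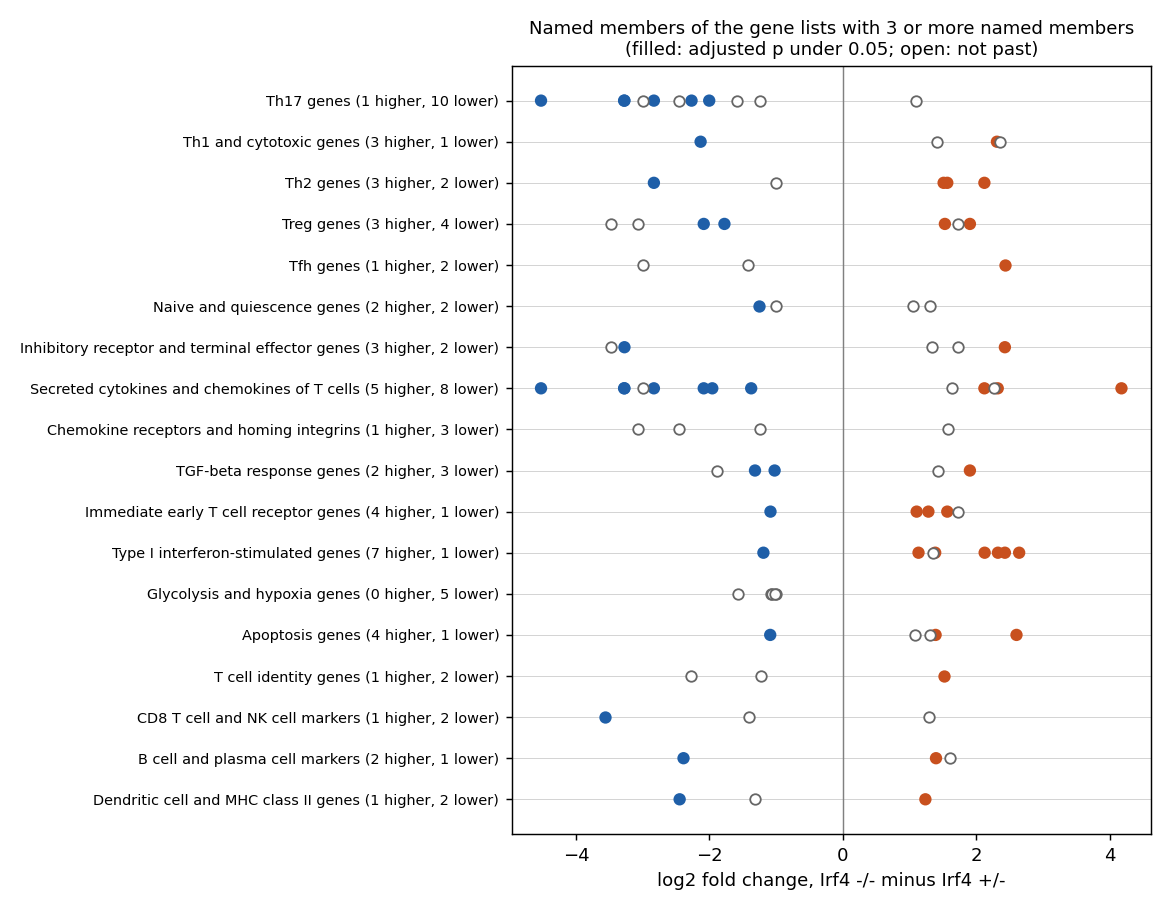
Log2 fold change of null over heterozygous cells (horizontal axis) for the named members of the 18 gene lists with at least 3 of them, with 1 point per gene; filled points passed a limma adjusted p of 0.05 and open points did not. In the Th17 list 10 of 11 members lie below 0, and in the interferon list 7 of 8 lie above 0.

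Over the 18 lists tested, 0 passed the adjusted threshold and 2 had an unadjusted Fisher p under 0.05. Since each named gene had been selected by the authors for a difference between these same samples, the direction of a list is not independent evidence.

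The authors' deposited table lists 427 probes as lower and 401 as higher in null cells. Recomputed from the values at its 2 limits, the selection gave 828 probes, all of them listed. Tested probe by probe, 725 probes passed a limma adjusted p of 0.05, of which 484 are in the authors' deposited table and 241 are not. The largest change among the latter was 1.0 on the log2 scale, a limit largely set by the authors' 2-fold selection on the same samples. The other 344 listed probes did not pass. The methods' t-test gave 4936 probes with an unadjusted p under 0.05 and 856 after Benjamini-Hochberg adjustment, 251 of them listed.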

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

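Treating exact zeros as missing and scaling arrays to 1 spread were chosen after the data were seen. Of 551 genes and unnamed probes past the threshold in null against heterozygous cells, the number became 1834 without the most variable 25% of probes, 1296 at an adjusted p under 0.1, 361 with a fold change of at least 2, and 9419 with array weights, where null replicate 2 received a weight of 41.4 and the estimation stopped before it converged. Leaving out 1 sample gave 30 to 239. Fewer samples lower recovery in simulation too, as the processing account gives. The other settings, apart from the replicate block, gave 385 to 777. The split of 286 higher and 265 lower became 292 and 191 with centring, 261 and 188 with quantile normalization, and 817 and 1017 without the most variable probes. Calls shared with the authors' deposited table numbered 361, against 201 with the methods' t-test and 30 to 212 with 1 sample left out, as separate counts. Both selections used the same samples, so shared calls are not independent evidence. The cause of the other shifts was not tested.

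With the replicate block, 13 passed, all 13 shared with the authors' deposited table, and Irf4 had a log2 fold change of -2.27 with a limma adjusted p of 0.0534. Of the 67 other genes named in the text by the rule, 51 that had passed without the block did not pass with it. Over the other settings the Irf4 adjusted p was 7.9e-05 to 0.0334. Deviations of same-numbered samples correlated at 0.097, -0.013 and -0.037, and not every sample correlated best with its own number. These values give no clear sign that the numbers pair the samples, but with 3 samples per group they cannot exclude it.

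None of the 67 other genes named by the rule reversed under a setting that tested it. Their groups do not overlap and they were selected for size, so leaving out a sample or adding the block cannot turn them. The number that lost the threshold was 1 with centring, 1 with quantile normalization, 3 with scaling, 1 with zeros as missing, 2 with robust variances, 2 with the least variable probe, 19 with the methods' t-test and 17 to 44 with 1 sample left out. With zeros as missing, Gja3 and Ildr1 could not be tested, and leaving out the most variable probes left 42 of the 67. No value was missing, so the setting with complete genes moved nothing. No gene list passed with the block, centring, quantile normalization, the least variable probe, the most variable probes left out, array weights, zeros as missing, scaling or 1 sample left out; these settings say little of the list result, since it rests on the signs of selected genes, and the other settings were not run on the lists. Camera with an estimated correlation and fry were not run. Signal over background is unknown.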

Other observations

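The tests of neighbouring genes against random placement and of their shared direction, the test of the region beside Irf4 and the test for heterozygous cells among null samples were chosen after the results were seen, as were the genes in the next paragraph and Mapkapk2, Exoc2 and Serpinb1c.

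Named members of the interferon-inducible p200 family, which bind nucleic acids in the cell, rose. Each had been selected by the authors for change, and the family was not tested as a set. Ifi203, Ifi204, Ifi209 and Ifi211 had log2 fold changes of 3.32, 2.70, 3.11 and 2.63 (limma adjusted p 0.00655, 0.00652, 0.0327 and 0.0128), beside Ifi206. They lie near each other in the genome and belong to 1 family, so cross-hybridisation between their probes was not excluded. Epsti1, another interferon-inducible gene, rose with a log2 fold change of 2.24, while the interferon-inducible chemokine gene Cxcl10 fell by 3.49. The receptor gene Egfr rose with a log2 fold change of 2.30 over its 4 listed probes, and its ligand genes Areg and Hbegf rose with 2.12 and 1.30. The TIM family gene Timd2 fell by 3.25 and Cysltr1, a leukotriene receptor gene, fell by 3.50, as Havcr1 and Ltb4r1 did, whereas Havcr2, another TIM family gene, had a log2 fold change of 1.73 (limma adjusted p = 0.057). Cyp11a1, which encodes the first enzyme of steroid synthesis, fell by 3.05 (adjusted p = 0.00112).

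Among 645 named genes placed in gene order, 153 pairs lay within 5 protein-coding genes of each other, against a mean of 104 in 10000 random sets drawn without predicted genes and large receptor families (permutation p = 0.0001, the smallest these draws can give). This is more than random placement among such protein-coding genes gave. The sets were not drawn from the genes on the array, so chance placement among measurable genes was not tested. Predicted genes and members of large receptor families were kept among the named genes, so observed and random sets were not fully alike. Without pairs that share a symbol root, 119 remained (random mean 96.6, permutation p = 0.016, and 0.006 and 0.18 within 2 and 10 genes), but when 3 gene families with differing symbols were also removed, a rule added after that count was seen, 112 remained (permutation p = 0.062). With these families removed the permutation p was 0.021 within 2 genes and 0.34 within 10, and against all protein-coding genes it was 0.0015, 0.001 and 0.0065 within 2, 5 and 10 genes, so whether related genes may account for the whole excess depends on the window and background and stays open. Of the 119 pairs, 79 changed in the same direction against 59.6 under shuffled directions (permutation p = 0.0005), and of the 112 pairs 73 did against 56.0 (permutation p = 0.0018), which argues against independent changes of neighbours; Il10 with Mapkapk2 and Cd86 with Ildr1 are directly adjacent pairs that both fell. The genes represented on the array are not known here, so shared regulation remains a hypothesis.

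The gene directly beside Irf4, Exoc2, rose with a log2 fold change of 1.70 (SE 0.13, limma adjusted p = 0.00776) on its 2 listed probes. DNA from a donor strain or the targeted allele itself might alter genes near Irf4. The 40 protein-coding genes nearest to Irf4 held named genes of 2 symbol roots, Exoc2 and the Serpinb1 group, against a median of 1 and a 95th percentile of 3 in windows around other genes, so the effect of flanking DNA and that of Irf4 loss cannot be told apart for them. Serpinb1c, 10 genes away, fell by 2.23 (adjusted p = 0.0266).

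Null replicate 1 stood apart from null replicates 2 and 3, with a root mean square distance 1.31 times that between these 2. With arrays scaled to 1 spread the ratio was 1.396, and over probes with no exact 0 it was 1.334. This argues against uniformly compressed ratios and against ratios of exactly 0 as the whole cause. Without intensities and flags, compression that varies with signal and failed estimates at other values could not be tested. Heterozygous cells in replicates 2 and 3 would raise Irf4. On component 1, replicate 3 lay 59.6% of the way from replicate 1 to the heterozygous mean. Its linear Irf4 ratio lay 1.98% of the way from replicate 1 to the heterozygous value. The null Irf4 values spanned 0.109 on the log2 scale. Component 1 was computed on log2 ratios, so these shares are on different scales and cannot be compared directly. A difference between the cultures or animals, or between hybridisations, stays open and was not tested.

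Of the 10 ways to split the 6 samples into 3 and 3, only 1, the real one, gave as many as 551 genes and unnamed probes past the threshold, and the highest other split gave 0 by limma. Every other split mixed the genotypes in both groups, so a difference between genotypes would widen the spread within its groups and lower its count. With 10 splits no share under 0.05 can be reached.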
